A study of Dendrobium officinale with 6 samples.

How the data were processed

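Leaves of Dendrobium officinale, an orchid grown as a medicinal plant, were sampled after a spray of methyl jasmonate (MeJA), the methyl ester of the plant hormone jasmonic acid, or of ethanol solvent alone. Per the labels' protocols, the plants were 6 months old and were kept at 25 °C with 12 h of light per day. MeJA was applied at 100 µM and the treated leaves were taken at 24 h. No sampling time was found for the control leaves. If it differed, its effect cannot be told apart from that of MeJA. Total RNA from the leaves was made into libraries by Illumina protocols and sequenced, with 3 control and 3 MeJA libraries, and the group and library number of each were taken from its title. The labels do not say whether the libraries of a group came from separate plants. The p-values therefore measure only the spread between these libraries, which can be technical.

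The authors deposited, for each library, 1 value per assembled gene, with 60597 genes listed under the same identifiers in all 6 libraries. No header or label names the unit. The deposited values were read as TPM (transcript abundance corrected for length and scaled to a common sum), because each library summed to 1000000 within rounding and because its low values fell on no step common to all genes, whereas reads scaled by library size alone would do so. The identifiers have the form that the Trinity assembler writes, with a graph component and a gene number within it. The assembler version, the tool that quantified the reads, the filters and the annotation are not given in the sources used here. TPM keeps no read depth, so the depth behind each value is unknown, whole reads were not recovered, and no count model or counting interval was used. A value of 0 is reported as listed at 0. Genes with near-identical copies are uncertain, since how reads were shared between copies is not stated.

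The files pair no identifier with a gene name or sequence, and no annotation was used here. The 38 lists of genes fixed by product name before the data were examined (jasmonate biosynthesis, terpenoid and alkaloid enzymes, photosynthesis, cell type markers and others) were therefore not applied, and none of them gives a result. For the same reason no chromosomal position is given. The rule for named genes was also fixed then. It takes the genes with the largest rise and the largest fall in log2 fold change among those past the threshold, with all 3 MeJA libraries on one side of all 3 controls, and, without names, prints at most 2 identifiers per direction. The 3 genes with the highest mean over all libraries, which the rule also takes, are described by rank.

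MeJA and control libraries were compared with limma (version 3.58.1, in R 4.3.3) on log2(TPM + 1), with an intensity trend in the prior variance and group as the only term. Genes with a mean of at least 1 TPM over the 6 libraries were tested, and a gene was called at a two-sided Benjamini-Hochberg adjusted p under 0.05. A fold change is on the log2(TPM + 1) scale and understates the change of low genes. Values per library were compared by a two-sided exact permutation test, which cannot go below 0.1 for 3 libraries against 3. The relation among the libraries of a group was described in 2 ways. The first was the share of genes at which a library held the middle of the 3 values, with an exact Clopper-Pearson interval at the 95% level. The second was the position of a library on the straight line between the other 2, for genes with a group mean of at least 100 TPM at which those 2 differed by at least 0.5 of their mean.

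The gene test was tested on simulated data for this comparison, with 60597 genes drawn from the control means and the spread of each gene. Of the 100 genes changed by 1 on the log2 scale, 39% were called, and of the 100 changed by 2, 64%, each with the right sign. Of the 111 genes called, 8 were unchanged in the simulation. The changed genes were drawn from those with a control mean of at least 5 TPM, and the simulated libraries were independent. Far fewer genes were changed than were called in the data, so these shares do not carry over to the real test. The alternatives were median-ratio size factors, quantile normalization, no filter on low values, a minimum mean of 5 TPM, a pseudocount of 0.1, no intensity trend, a minimum change of 2-fold, full separation of the groups, the library number as a block and each library left out. The fit on libraries 2 and 3 of each group alone was added after the data were seen. A second expression unit was not in these files, so that alternative was not run.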

Results

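Transcript levels were measured by RNA sequencing in leaves of Dendrobium officinale sprayed with 100 µM MeJA and taken at 24 h. They were compared with leaves sprayed with ethanol solvent, whose sampling time is not known, with 3 libraries in each group. The study set out to find genes whose regulation accompanies the accumulation of alkaloids under MeJA. Levels were given for 60597 genes of a de novo assembly, in TPM, and read depth is unknown. The genes carry assembly identifiers and no names here, so the changes are described by size, level and library.

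The 6 libraries divided by treatment. Pearson's r of log2(TPM + 1) across genes, which are not independent replicates, was 0.912 to 0.926 within the control group and 0.894 to 0.929 within the MeJA group, against 0.838 to 0.856 between the groups. The first principal component held 47.9% of the variance over the tested genes. On it the controls lay at -93.6 to -91.0 and the MeJA libraries at 70.5 to 112.4. No pair of libraries held the same value at more than 0.82% of the genes above 0 in either of them. Control library 1 and MeJA library 1 did so at 0.68%, against 0.10% to 0.19% for the other 8 pairs between the groups. Within the control group the share was 0.58% for libraries 1 and 2, against 0.27% and 0.24% for the other pairs. Within the MeJA group it was 0.82% for libraries 1 and 3, against 0.23% and 0.18%. The number of genes at 1 TPM or more was 51107 ± 274 in controls and 48404 ± 2480 under MeJA (SD, n = 3 each), and every MeJA library lay below every control (two-sided exact permutation p = 0.1, the smallest that 3 against 3 can give, and 0.15 after adjustment over 12 library measures). The difference, MeJA minus control, was -2703 genes, but -575 under median-ratio size factors and -1325 without MeJA library 3, which held the fewest, 45648.

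MeJA was followed by changes of up to about 7 log2 units in single genes. The gene with the largest rise, TRINITY_DN17233_c0_g2, went from 0.92 ± 0.70 TPM in controls to 440.1 ± 328 TPM under MeJA (SD, n = 3 each), a log2 fold change of 7.44 ± 0.78 (SE, limma adjusted p = 0.0024). Its MeJA level ranged from 86.8 TPM in library 2 to 735 TPM in library 3. TRINITY_DN15527_c2_g2 rose from 2.99 ± 1.25 to 529 ± 125 TPM, a log2 fold change of 7.07 ± 0.25 (limma adjusted p = 0.000144). In the other direction, TRINITY_DN10543_c0_g1 fell from 60.3 ± 25.4 to 0.41 ± 0.24 TPM, a log2 fold change of -5.36 ± 0.33 (limma adjusted p = 0.000466). TRINITY_DN18847_c2_g1 fell from 57.0 ± 8.2 to 0.75 ± 1.03 TPM and was listed at 0 in MeJA library 1, with a log2 fold change of -5.19 ± 0.39 (limma adjusted p = 0.000833). With libraries 2 and 3 of each group alone, TRINITY_DN15527_c2_g2 stayed past the threshold, while the other 3 genes, in the order given, had log2 fold changes of 7.12, -5.30 and -4.84 at limma adjusted p values of 0.0857, 0.0521 and 0.0504. The 4 genes following in rank among those that rose had mean MeJA levels of 526 to 1756 TPM, 63.6 to 228 times their control means.

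**Figure D1:**
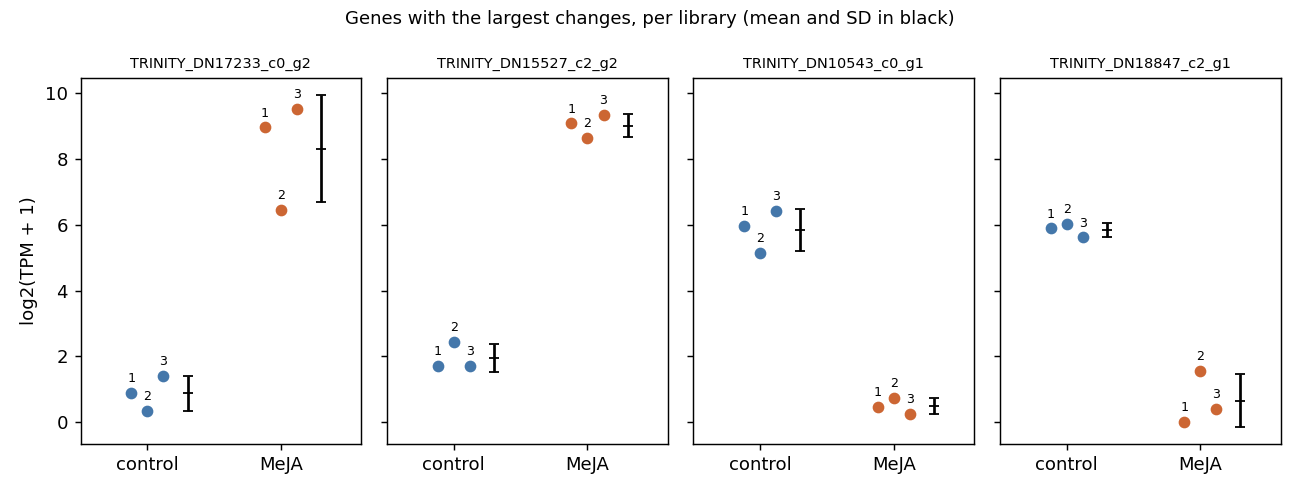
Level of the 4 named genes in each library, as log2(TPM + 1) on the vertical axis, with the groups on the horizontal axis, points numbered by library and the mean and SD (n = 3) in black. At each gene the MeJA libraries lie apart from the controls, and at TRINITY_DN17233_c0_g2 MeJA library 2 lies below the other MeJA libraries.

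Of the 55498 genes tested, 10381 (18.7%) were called, with 3415 higher and 6966 lower under MeJA (limma, adjusted p under 0.05). In each of the 10381 genes the 3 MeJA libraries lay on one side of the 3 controls. A call requires a group difference that is large against the spread, so this separation largely follows from the call. Over all tested genes 39.7% were separated in this way, where chance gives 10% if the 6 libraries are independent. Chance gives more where library 1 of each group lies between libraries 2 and 3, as described below. A shift of all values by scaling would also raise the share. At least 2-fold changes were found in 2345 higher and 2731 lower genes, and under median-ratio size factors in 2867 higher and 1801 lower genes. The larger changes on the log2(TPM + 1) scale were mainly rises. On this scale a fall cannot exceed the control level and a rise cannot exceed the MeJA level. A gene low in controls therefore has little room to fall but can still rise. At a mean of 100 to 1000 TPM, where 2-fold falls are not limited in this way, 186 genes were at least 2-fold higher and 60 lower. At least 4-fold changes were found in 788 higher and 491 lower genes, at least 8-fold changes in 203 higher and 37 lower genes, and at least 16-fold changes in 58 higher and 3 lower genes. The count depended on single libraries. It was 4300 without control library 1, 6073 without control library 2, 5653 without control library 3, 4494 without MeJA library 1, 11820 without MeJA library 2 and 7554 without MeJA library 3. With libraries 2 and 3 of each group alone, 129 genes were called, 109 higher and 20 lower, and each of the 129 was also called with all 6 libraries. These libraries are among the 6, so the overlap is not independent evidence.

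The split between directions depended on the scaling. The median log2 fold change of all tested genes was -0.17 in the deposited values, where 67.1% of the calls were lower. Median-ratio size factors brought the median to -0.01. Relative to that shift, 4493 genes were higher and 3737 lower, so that 45.4% of the calls were lower. Quantile normalization gave a median of -0.06, with 4148 genes higher and 5610 lower, so that 57.5% of the calls were lower. Under the size factors, rises still outnumbered falls among at least 4-fold changes, with 957 higher and 348 lower genes, and among at least 8-fold changes, with 244 higher and 23 lower genes. The limit that the control level sets on falls of low genes holds there too. At 100 to 1000 TPM, 225 genes were at least 2-fold higher and 36 lower under the size factors.

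**Figure D2:**
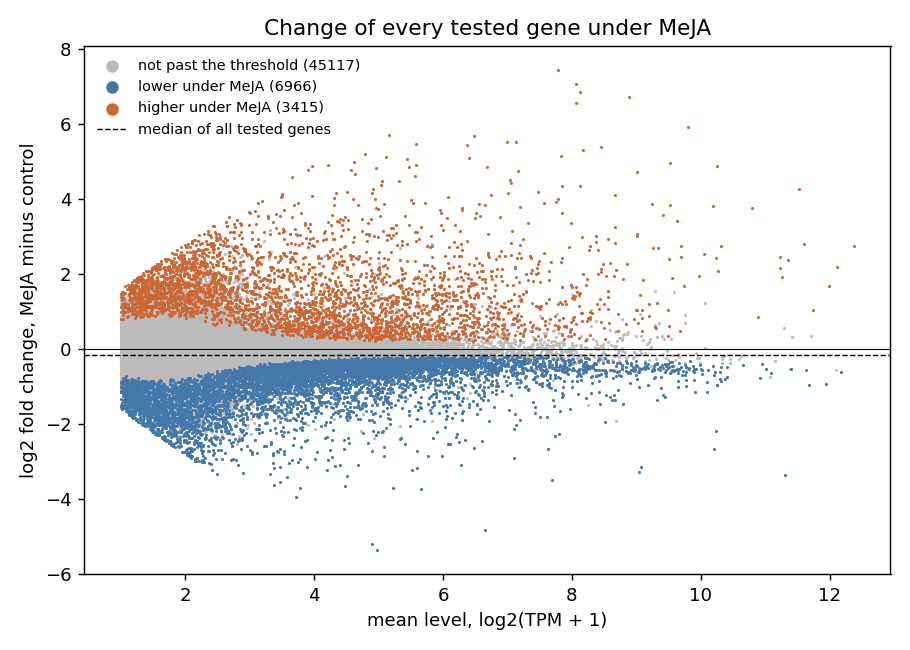
Log2 fold change of each tested gene (MeJA minus control, vertical axis) against its mean level as log2(TPM + 1) (horizontal axis), coloured by call at a limma adjusted p under 0.05. The 3415 higher genes reach 7.44 and the 6966 lower genes reach -5.36, and the dashed line marks the median of -0.17.

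Abundant genes were called more often than low genes. The chance of a call also depends on level, since the log2(TPM + 1) scale understates changes of low genes. These rates therefore do not compare how often abundant and low genes responded. Among genes with a mean of 1 to 5 TPM, 3.3% were higher and 5.7% lower. Among the 12710 genes at 10 to 100 TPM, 11.7% were higher and 27.2% lower, and among the 1408 genes at 100 to 1000 TPM, 22.5% were higher and 41.2% lower. Of the 70 genes at 1000 TPM or more, 19 were higher and 32 lower. At least 2-fold changes in this top class were found in 18 higher and 4 lower genes. Under median-ratio size factors the classes from 1 to 1000 TPM held more higher than lower calls, for instance 16.8% higher and 12.6% lower at 10 to 100 TPM, and the top class held 19 higher and 20 lower genes.

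The most abundant genes changed rank. The gene with the highest mean over all libraries rose from 1273 ± 110 to 9349 ± 4263 TPM (SD, n = 3 each), a log2 fold change of 2.76 ± 0.37 (limma adjusted p = 0.00536). The gene ranked 2 fell from 5576 ± 196 to 3628 ± 232 TPM, a log2 fold change of -0.62 ± 0.16 (limma adjusted p = 0.0418). The gene ranked 3 rose from 1361 ± 154 to 7479 ± 4770 TPM, a log2 fold change of 2.18 ± 0.56 (limma adjusted p = 0.0408). At ranks 1 and 3, MeJA library 2 held 4731 and 2412 TPM and MeJA library 3 held 13135 and 11882 TPM. The genes called higher made up 8.76% ± 0.02 of all TPM in controls and 27.2% ± 3.6 under MeJA. The genes called lower made up 42.6% ± 0.1 and 26.6% ± 1.9. These sets were chosen on the same libraries, so the shares describe the size of the change and are not independent evidence of it. The 10 most abundant genes of each library took 4.14% ± 0.14 of all TPM in controls and 5.87% ± 2.05 under MeJA, a difference smaller than the spread of the MeJA libraries (two-sided exact permutation p = 0.4). That difference was 1.73 percentage points, 0.705 without MeJA library 3 and 2.75 without MeJA library 2.

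Some genes were listed in a single group. In 98 genes the 3 controls were listed at 0 and each MeJA library held at least 1 TPM, and 6 of these genes had a mean of 10 TPM or more, up to 69.8 TPM. The reverse was found in 165 genes, whose control means reached 9.27 TPM. With depth unknown, a value of 0 does not show that a gene was silent, and no fold is given for these genes.

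In both groups, library 1 held the middle value of the 3 libraries more often than libraries 2 and 3 did, and most often among abundant genes. Among genes with a mean of at least 100 TPM, library 1 held the middle value at 65.4% of 1478 genes in controls (95% exact interval 62.9% to 67.8%) and at 81.1% of 1478 genes under MeJA (79.0% to 83.0%). The values for libraries 2 and 3 were 18.5% and 16.2% in controls and 8.4% and 10.6% under MeJA. At 10 to 100 TPM library 1 was in the middle at 49.9% of genes in controls and 61.5% under MeJA. At 1 to 10 TPM, where most genes lie, it was in the middle at 38.1% of 40048 control genes and 45.9% of 39481 MeJA genes, against 33.3% for libraries that take the middle equally often. Genes within a library are not independent, so the intervals are too narrow. At genes of at least 100 TPM that differed strongly between libraries 2 and 3, the median position of library 1 on the line from library 2 (0) to library 3 (1) was 0.53 in controls (quartiles 0.49 and 0.55, 51 genes) and 0.58 under MeJA (quartiles 0.55 and 0.62, 175 genes). It lay between 0 and 1 at 100% of these genes in both groups. Choosing genes at which libraries 2 and 3 lie far apart favours a place between them for library 1. At genes chosen in this way from the other 2 libraries, libraries 2 and 3 lay between them at 0% in both groups. These were 14 and 8 genes in controls and 8 and 59 genes under MeJA. The limma test takes the 3 libraries of a group as independent, and where they are not, its p-values are too small and its counts of calls too high.

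**Figure D3:**
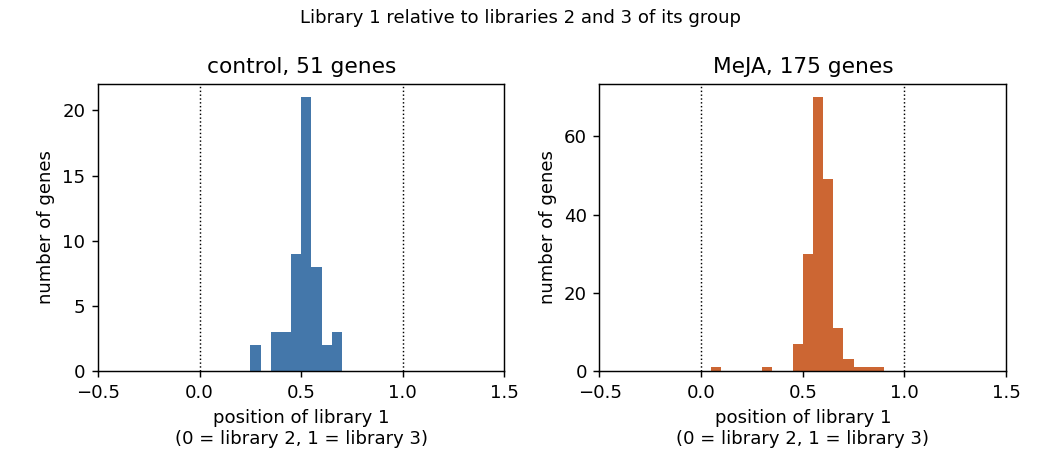
Number of genes (vertical axis) by the position of library 1 on the line from library 2 (0) to library 3 (1) of its group (horizontal axis), for genes with a group mean of at least 100 TPM at which libraries 2 and 3 differ by at least 0.5 of their mean. The 51 control genes centre on 0.53 and the 175 MeJA genes on 0.58, all between the dotted lines at 0 and 1.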

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

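The fit on libraries 2 and 3 alone was chosen after the data were seen, and the other settings before. From 10381 calls (3415 higher, 6966 lower), the count became 5076 with a minimum change of 2-fold (2731 lower) and 22026 by full separation of the groups (6527 higher, 15499 lower). Chance separates 10% of genes if the 6 libraries are independent, and more where library 1 lies between the others of its group. Lower calls were 3737 under median-ratio size factors and 4571 without the intensity trend, and the cause of the latter was not tested. Leaving out 1 library gave 4300 to 11820 calls, 1681 to 3539 higher and 2471 to 8281 lower, with fewer libraries in each fit. The highest counts came without MeJA library 2, and the lowest without control library 1 for all and lower calls and without MeJA library 1 for higher calls. Libraries 2 and 3 of each group alone gave 129 calls (109 higher, 20 lower). The library number as a replicate block gave 5748 calls (2175 higher, 3573 lower). Deviations of same-numbered libraries correlated at 0.020, -0.013 and -0.007, and 2 of the 6 libraries correlated best with their own number. These correlations give no sign that the numbers pair the samples but, with so few libraries, cannot exclude it. The libraries numbered 1 shared more identical values (0.68% of the genes above 0 in either) than the other pairs between the groups. The cause was not tested, so these values do not show that the numbers pair the samples. Quantile normalization, no filter, a minimum mean of 5 TPM and a pseudocount of 0.1 kept the counts within 1.5 times, at 9758, 10325, 9034 and 9258 calls. Over their 14 alternatives the 4 named genes had log2 fold changes of 6.84 to 8.56, 6.91 to 7.46, -6.91 to -5.07 and -7.00 to -4.84 in the order of the report. The lists fixed by product name, and every alternative for them, were not run, since the identifiers carry no names. Read depth is unknown, which limits what can be said of genes at few TPM and of values of 0.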

Other observations

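The tests on the share of genes with library 1 in the middle, on size factors and on the library in which called genes changed more, with its limit of 75%, and the fits on 2 libraries per group, were chosen after their results or the pattern had been seen. The shuffling of directions within components had no prediction written first. The other tests were written down first.

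Assembled genes of 1 Trinity component, which share part of their sequence graph, tended to change together. Of 2684 pairs of called genes in the same component, 2012 (75%) were called in the same direction. Shuffling the directions among the called genes gave 55.9% on average and 59.2% at most (permutation p = 0.000999, the smallest that 1000 shuffles can give). The 10381 calls fell in 8345 components, of which 441 held calls in both directions. Genes are not independent replicates, and fragments of 1 transcript can be listed as separate genes.

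In both groups library 1 took the middle of the 3 values more often than the other libraries, at 65.4% of genes of at least 100 TPM in controls and 81.1% under MeJA, but at 38.1% and 45.9% of genes at 1 to 10 TPM. A calculation from the values or reads of libraries 2 and 3 is argued against, since it would leave a gene at 0 wherever both are at 0, and 51.6% of such genes in controls and 54.5% under MeJA had a value above 0 in library 1, a share like that of libraries 2 and 3 against their own others (50.8% and 57.5% in controls, 53.3% and 48.5% under MeJA). A difference in the strength of the MeJA response would not order the controls, but under MeJA it predicts the same middle place as a pool. It would also make called genes change more in 1 and the same library. Of 105 called genes with a MeJA mean of at least 100 TPM that differed strongly between MeJA libraries 2 and 3, 79 changed more in library 3 and 26 in library 2. By direction, 64 of 90 higher genes and 15 of 15 lower genes changed more in library 3. Over all 105 genes the larger share was 75.2%, and its 95% exact interval, 65.9% to 83.1%, includes the limit of 75%. That limit was set after the result or the pattern had been seen. A pool says nothing on which of libraries 2 and 3 changes more, so this share cannot tell response strength and a pool apart. The 26 genes do not follow a single strength. On the first principal component, which separates the groups, MeJA libraries 1, 2 and 3 lay at 93.7, 70.5 and 112.4. On the second, with 17.8% of the variance, they lay further apart, at 6.1, -110.1 and 82.2. A strength that scales every change alike would spread them along the first, so it does not describe their distance on the second. It may still contribute to their order on the first. A pool of the material behind libraries 2 and 3 predicts 1 position for genes higher in either, and the difference of the medians was -0.013 in controls (95% bootstrap interval -0.042 to 0.039) and -0.003 under MeJA (-0.019 to 0.016), which does not exclude a pool but is also what libraries that vary along a single axis would give, so both stay open. If library 1 were a pool, each group would hold 2 independent libraries, and the limma p-values would be too small and the 10381 calls too many.

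Fits on 2 libraries per group gave 3493 to 8458 calls in the 4 subsets that kept both libraries numbered 1, 640 to 5432 in the 4 that dropped 1 of them, and 129 in the subset without either. At an unadjusted p under 0.05 the gap was smaller, with 10775 genes without either and 14728 to 17951 in the subsets with both. Leaving out the library in the middle leaves the libraries that lie furthest apart, so the fall follows from the pattern and is not independent evidence of a pool.

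More genes were lower than higher under MeJA, 67.1% of the calls. Counting fragments of the same component repeatedly is argued against as the cause, since counting each component at most 1 time per direction left 67.1% lower. The share was 45.4% with median-ratio size factors, which bring the median change close to 0 by construction and so decide nothing on the cause, and 57.5% with quantile normalization. Scaling to a common sum and a true decrease of many transcripts cannot be told apart here, because the labels and values used give no total RNA per leaf.

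In 672 pairs, called genes of the same component moved in opposite directions. If reads were shared between near-identical copies, such pairs would vary against each other within groups more than opposed pairs of different components. The difference of the median correlations was -0.039, with a 95% bootstrap interval of -0.129 to 0.040. The interval includes 0, so shared reads and separate regulation of related genes cannot be told apart for these pairs.

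With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. Of the 10, 1 gave 10381 or more genes, the real one, and the highest of the other splits gave 0 with limma, with at most 2494 genes at an unadjusted p under 0.05 against 18594 in the real split. Each other split mixes MeJA and control libraries in both groups, which adds the treatment difference to the spread and lowers the counts. These counts therefore do not show what chance alone would give.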
